A study of Homo sapiens with 18 samples.

How the data were processed

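Total RNA was labelled as biotinylated cRNA and hybridised to Affymetrix 3′ expression arrays, per the labels' protocols. The series holds 18 arrays, all from kidney transplant recipients treated with sirolimus, an inhibitor of the mTOR kinase. Per the series' design text, 30 recipients took part in a randomized trial of late conversion to sirolimus (18 recipients) against staying on tacrolimus (12 recipients), with sampling 0, 6, 12 and 24 months after randomization. Arrays from recipients on tacrolimus were not analysed here, and the labels of the 18 arrays give no time point. The sources disagree on the material: the source field names kidney biopsies, while the tissue field and the design text name peripheral blood. All 18 arrays formed 1 group, so no groups were compared, and the spread between arrays was described. The arrays are numbered 1 to 18 in the order of deposit, which is only a name. Nothing in the labels of the single arrays says that each came from a different recipient. The tests took the 18 arrays as independent, so the p-values may be too small if some arrays share a recipient.

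The deposited table holds log2 probe-set levels made with RMA (robust multi-array average: background correction, quantile normalization and median polish over the arrays run together), per the submitters' processing notes. The version of RMA, and whether the 18 arrays were processed alone or with others, are not given in the sources used here. The 22277 probe sets had values from 2.04 to 14.66, and the medians of the arrays lay between 5.68 and 5.89, as log2 levels. Interquartile ranges of the arrays ran from 2.89 to 3.49, so the arrays did not share 1 distribution. A difference of 1 on this scale is a doubling after RMA, and RMA background leaves low levels compressed. An array gives no read depth; the number of arrays limits the precision. Pairs of arrays correlated at 0.940 to 0.992 over all probe sets (median 0.969), and 0 pairs were identical.

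Probe sets were named from the platform annotation: 19070 had 1 gene, 1043 had several and 2164 had none listed. Of the probe sets with 1 gene, 19058 were matched by gene identifier to the human gene table to update their symbols and 12 were not. Probe sets with several genes or none were left unnamed and unused, as were 24 genes that are XIST or Y linked and the 62 control probe sets. Each of the 11939 remaining genes was represented by its probe set with the highest mean level; 4304 genes had several. Where probe sets of a named gene disagreed, this is stated with the gene. Probe sets differ in affinity, so a gene's level was not taken as an amount of its transcript. Orders and percentiles of lists, and the placing of genes by level, carry this limit.

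Lists of 35 cell types, tissues and programmes were fixed before the data were examined, from textbook markers, and some of their genes are expressed by more cell types than the list's name says. For each cell-type or tissue list the median log2 level of its members was taken on every array and given a percentile among 10000 random gene lists of the same size. For co-variation, the mean pairwise Pearson correlation of a list's members over arrays was set against 10000 random lists matched on mean level in 20 bins, one-sided, with Benjamini-Hochberg adjustment over the 35 lists. A list's score on an array is the mean z-score of its members. For 13 core lists, all 78 pairs of scores were correlated (Pearson and Spearman, two-sided tests with 100000 permutations, Benjamini-Hochberg adjustment over the pairs), and again without the 2 arrays farthest from the median of the first score.

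For 5 scores fixed before the data were examined (regulatory T cells, cytotoxic lymphocytes, erythroid cells, type I interferon response and kidney proximal tubule), the log2 level of every gene was fitted on the standardised score with limma 3.58.1 (lmFit and eBayes with a trend, R 4.3.3). The list's own members were left out, as were genes in the lowest 25 percent of mean level, and the threshold was an adjusted p of 0.05. A slope is the change in log2 level per SD of the score. The order of the scores over arrays was also permuted, to 100 orderings with the real one included. RNA quality was described by the mean 3′ minus 5′ difference of the ACTB and GAPDH control probe sets, which was 4.25 ± 0.86 for ACTB and 1.38 ± 0.84 for GAPDH (log2, SD, n = 18); a larger difference is usual for more degraded RNA or less complete labelling. No scan date or batch was in the labels or the table. The other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

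The genes named in the text followed a rule fixed before the data were examined. They are the 25 genes with the largest SD among genes above the median gene; for each of the 5 fits, up to 6 genes with the most positive and 6 with the most negative slope past the threshold; for each list described, the members with the highest and lowest mean correlation to the other members and the most variable member; and FOXP3, IL2RA, CTLA4, FKBP1A, MTOR, IL2 and FKBP5 in every case. Other genes are named only where a count of 5 or fewer members called for it, or where it is said that they were chosen after their values were seen.

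The alternatives fixed before the data were examined were the median of a gene's probe sets, quantile normalization again, centring of arrays, other filters on level, the first principal component (29.7% of the variance) or the 3′ minus 5′ difference as a covariate, the mean log2 level as the score, Spearman correlation, limma without trend or with array weights, FOXP3 alone as a score, the T-cell score as a covariate, the median absolute deviation in place of the SD, the mean of a list's members, and each array left out in turn. Added after seeing the data were the mean of the lowest 25 percent of genes as a covariate, and the data without the 3 arrays of largest 3′ minus 5′ difference. That mean stands for background signal only in part.

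The steps were tested on simulated data. For the fits these kept each gene's mean and SD on these arrays and let genes vary independently, which real genes do not. Of 100 genes with a planted slope of 0.5, the fits recovered 93 for regulatory T cells, 82 for cytotoxic lymphocytes, 90 for erythroid cells, 86 for type I interferon response and 82 for proximal tubule, and of 100 genes with a slope of 1 at least 98 for each score. The fits made between 6 and 13 false calls per score among the 8932 to 8951 genes tested. The list test called 4 of 5 lists planted with a shared correlation of 0.2, 5 of 5 at 0.4 and 0 of 25 with none. The test of score pairs called 113 of 120 pairs planted at a correlation of 0.85 and 5 of 1440 planted at 0.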

Results

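Gene expression was measured on 18 arrays from kidney transplant recipients treated with sirolimus, an inhibitor of the mTOR kinase used against rejection. The study concerns immune profiles after conversion to this drug from tacrolimus, an inhibitor of calcineurin. The 18 arrays formed 1 group with no time point in their labels, and 11939 genes were measured on each. The labels name both kidney biopsies and peripheral blood as the material. The number of arrays limits the precision of all values.

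Transcripts of kidney tubules were among the highest on the arrays. Those of the proximal tubule, which reabsorbs most of the filtrate, had a median log2 level of 9.75 ± 0.48 (SD, n = 18), and all 15 measured members lay above the median gene, at 6.39. The list stood at percentile 99.99 of random gene lists on average and at 99.82 on the array where it was lowest. The loop of Henle and distal tubule list was at 9.80 ± 0.53 (percentile 99.9), with KNG1 at 12.42 ± 0.62 and CALB1, a calcium-binding protein, at 11.65 ± 0.86. Endothelium and fibroblasts stood at 8.37 ± 0.46 (98.4), podocytes, the filtering cells of the glomerulus, at 7.22 ± 0.36 (80.0) and the collecting duct at 6.15 ± 0.58 (41.1). With the median of each gene's probe sets, endothelium and fibroblasts were at 6.84.

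Lists of blood cells lay below the tubule lists. Among leukocytes the monocyte list was highest, at 6.89 ± 0.67 (percentile 67.8), followed by plasma cells at 5.97 ± 0.60 (36.9), cytotoxic lymphocytes at 5.86 ± 0.77 (30.1), dendritic cells at 5.72 ± 0.26 (27.1) and naive T cells at 5.69 ± 0.42 (23.8). Cytotoxic lymphocytes ranged from percentile 1.0 to 88.5 between arrays. T cells were at 5.39 ± 0.39 (11.8), natural killer cells at 5.05 ± 0.36 (7.55), B cells at 4.80 ± 0.41 (2.95) and regulatory T cells at 4.69 ± 0.22 (2.67). Red cells, platelets and granulocytes were between percentiles 0.04 and 21.1: erythroid cells at 5.77 ± 0.17 (21.1), platelets at 4.93 ± 0.24 (4.06), neutrophils at 5.04 ± 0.30 (3.76), eosinophils and basophils at 4.32 ± 0.28 (1.81) and immature neutrophils at 3.74 ± 0.13 (0.04). The lists of other tissues were at 4.94 ± 0.31 for liver (4.31), 4.72 ± 0.58 for brain (5.95) and 3.57 ± 0.40 for skeletal muscle (0.264). With the median of probe sets platelets were at 4.27, brain at 4.01 and liver at 4.33, and with the mean of the members eosinophils and basophils were at 5.2, plasma cells at 6.68 and liver at 5.56, so the order of these lists depends on the summary. The percentiles describe these arrays, carry no p-value, and depend on the affinity of the probes. On every array the proximal tubule list stood at percentile 99.82 or above, and the neutrophil list at 9.45 or below. These levels go with the kidney biopsies of the source field. They argue against the peripheral blood of the tissue field and the design text as the material of these arrays.

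**Figure D1:**
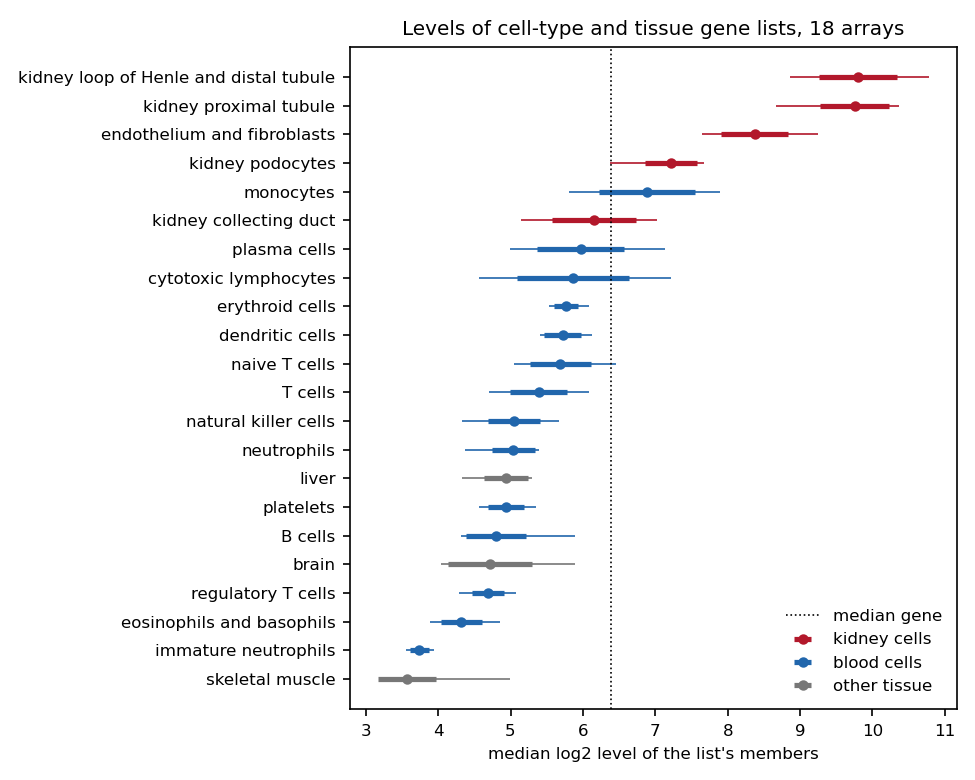
Median log2 level of the members of each cell-type and tissue list (x axis). Points are means over the 18 arrays, thick bars 1 SD, thin lines the range from the lowest to the highest array, and the dotted line the median gene at 6.39. The proximal tubule at 9.75 and the loop of Henle and distal tubule at 9.80 lie above all blood lists, of which monocytes at 6.89 are the highest.

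Members of 21 of the 35 lists varied together over the arrays more closely than random lists of the same level. The interferon gamma response had a mean pairwise correlation of 0.667 over 12 members (95th percentile of random lists 0.125). Its most variable member was CXCL11, a chemokine for activated T cells, at 6.20 ± 2.15. TAP1, the peptide transporter of antigen presentation, followed the other members best (mean r 0.768), and CIITA, the class II transactivator, least (0.364). Cytotoxic lymphocytes reached 0.504 over 15 members, led by CCL5 (0.666), with ADGRG1 at −0.113. Monocytes reached 0.473, with CLEC7A at 0.625, LYZ, the lysozyme gene, at 9.49 ± 1.29 and HMOX1 at −0.112. T cells had 0.353, led by CD3G of the T-cell receptor complex (0.563), whereas MAL, also expressed in kidney tubules, was at −0.327. The type I interferon response had 0.283, with RSAD2 at 0.50, IFI44L at 7.56 ± 0.78 and DHX58 at −0.253.

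Further immune lists past the threshold were regulatory T cells at 0.326 (adjusted p = 0.0102), B cells at 0.296 (0.0163), plasma cells at 0.293 (0.00754), natural killer cells at 0.281 (0.0206), inflammatory response at 0.252 (0.0070) and naive T cells at 0.186 (0.0206). FOXP3, the transcription factor of regulatory T cells, had the highest mean r of its list (0.518), and LRRC32 the lowest (−0.0412). TCL1A led the B cells (0.478), TNFRSF17 the plasma cells (0.461), KLRF1 the natural killer cells (0.417), CXCL8 the inflammatory list (0.398) and IL7R the naive T cells (0.367). The call for regulatory T cells ended with the 3′ minus 5′ difference as a covariate (mean r 0.140), with background as a covariate (−0.0197, although at r = 0.951 with the score this covariate nearly fixes the outcome), without the 3 arrays of largest 3′ minus 5′ difference (0.193), with the first principal component removed and with the median of probe sets, and the mean r was 0.176 with quantile normalization again. Without array 11, B cells fell to 0.188 and naive T cells to 0.123, and without array 8 natural killer cells fell to 0.217, and these calls ended. Centring the arrays, or leaving out the 3 arrays of largest 3′ minus 5′ difference, also ended the calls for B cells and naive T cells, and removing the first principal component that for natural killer cells.

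Among kidney lists, the proximal tubule had a mean correlation of 0.562 over 15 members, all positive, from SLC3A1 (0.332) to the organic anion transporter gene SLC22A8 (0.675). Podocytes reached 0.284 (adjusted p = 0.0070), with WT1 at 0.481, CLIC5 at 0.445 and TCF21 at −0.0967, and the collecting duct 0.242 (0.0049), led by HSD11B2 (0.396), and both calls ended with only genes above the median gene. With the first principal component removed the collecting duct was at 0.134. The loop of Henle and distal tubule (0.127, 0.114) and endothelium and fibroblasts (0.110, 0.0671) did not pass. Both passed with only genes above the median gene, and endothelium and fibroblasts also with quantile normalization again, with Spearman correlation and without array 16. Of the metabolic and growth programmes, oxidative phosphorylation varied together at 0.689, with NDUFA1 at 0.810 and ATP5MC3 at 0.295. Ribosomal proteins reached 0.357, with RPS18 at 0.573 and RPL8 at −0.359, and fell to 0.166 with quantile normalization again and to 0.152 with the first principal component removed. Proliferation had 0.245 (adjusted p = 0.0206), glycolysis and hypoxia 0.0928 (0.0300) and immediate early genes 0.144 (0.0212). Those 3 calls ended without array 6 (0.211), without array 10 or 13 (0.0758 without array 13) and without array 17 (0.0744), in that order. The glycolysis call also ended with quantile normalization again, arrays centred, the first principal component removed (0.00986), or the 3′ minus 5′ difference (0.0614) or background (0.0262) as a covariate. That of proliferation ended with the first principal component removed, and that of immediate early genes with arrays centred and with Spearman correlation. Skeletal muscle genes varied together at 0.603 and brain genes at 0.219 (0.0212), and the brain call ended with the 3′ minus 5′ difference (0.117) or background (−0.0282) as a covariate and in 3 other settings.

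The pathways that the drugs act on did not pass this test. The mTOR pathway components had a mean r of 0.106 (adjusted p = 0.0533), with TSC2 at 0.297 and EIF4E at −0.260, and passed in 6 of 18 leave-outs (arrays 9, 10, 12, 14, 15 and 16) and with Spearman correlation. Calcineurin and NFAT genes had −0.000612 (0.433), with NFATC3 at 0.171 and NFATC1 at −0.315. Neutrophils had 0.156 (0.0575), liver 0.147 (0.0575), platelets 0.147 (0.156), immature neutrophils 0.206 (0.333), eosinophils and basophils 0.119 (0.159), dendritic cells 0.0979 (0.218), glucocorticoid response 0.0540 (0.189), cholesterol synthesis 0.0309 (0.333), erythroid cells −0.00857 (0.688) and ATF4 targets −0.0153 (0.834). The neutrophil list passed without array 2, 5, 8, 12 or 17, with the median of probe sets, with Spearman correlation and without the 3 arrays of largest 3′ minus 5′ difference. The liver list passed without array 2, 5, 8, 10, 12, 13 or 17, with the 3′ minus 5′ difference as a covariate and without those 3 arrays. For 8 of the 21 called lists the adjusted p was 0.000437, which rests on the smallest p that 10000 random lists can give (1e-04).

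Scores of T cells, cytotoxic lymphocytes and monocytes rose and fell together. Over the 18 arrays T cells correlated with naive T cells at r = 0.886 (Spearman rho 0.899), with monocytes at 0.853 (0.831) and with cytotoxic lymphocytes at 0.845 (0.870), and cytotoxic lymphocytes with monocytes at 0.835 (0.901). Without the 2 farthest arrays these r were 0.865, 0.812, 0.768 and 0.863. Regulatory T cells did not pass the threshold with T cells (r = 0.452, rho 0.408, adjusted p = 0.167 by permutation, r 0.330 without the 2 farthest arrays). They correlated with platelets at 0.911 (0.897) and with neutrophils at 0.80 (0.909), and neutrophils with platelets at 0.766 (0.814), or 0.898, 0.796 and 0.784 without the 2 farthest arrays. With background as a covariate, which had r = 0.951 with the regulatory T-cell score and so left little of it, these r were −0.0692, 0.0932 and −0.179, and these calls ended. The last also ended with the 3′ minus 5′ difference as a covariate (0.567), with quantile normalization again (0.578) and with the first principal component removed (0.569). In all, 13 of 78 pairs passed, with permutation p for r from 1e-05, the smallest the permutations can give, to 0.00732 (adjusted 0.000195 to 0.0439).

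The other called pairs were weaker. Naive T cells correlated with cytotoxic lymphocytes at 0.645 (rho 0.701), lost without array 13 (0.604) or 17 (0.620), with monocytes at 0.662 (0.678), lost without array 9 (0.613) or 13 (0.624), and these r were 0.658 and 0.681 without the 2 farthest arrays. Their r with B cells was 0.702 (rho 0.589, adjusted p 0.0555), and this call ended with Spearman correlation, without array 11 (0.528), without the 2 farthest arrays (0.404) and without the 3 arrays of largest 3′ minus 5′ difference (0.367). The B-cell score of array 11 was 1.70 and the next highest 0.62. Type I interferon response correlated with ribosomal proteins at 0.641 (0.730), lost without array 4 (0.599), 8, 13 or 14 and without the 2 farthest arrays (0.553), with the first principal component removed (0.418) and without the 3 arrays of largest 3′ minus 5′ difference. Its pair with proliferation (0.602) kept its call only without array 1, 9, 11 or 16 (lowest r 0.548, and 0.676 without the 2 farthest arrays). It also lost it with the first principal component removed (0.397), the median of probe sets, quantile normalization again, Spearman correlation and background as a covariate. The pair of proliferation with ribosomal proteins (0.611, rho 0.614) kept its call only without array 5, 6, 11, 15 or 16 (lowest r 0.523), and lost it without the 2 farthest arrays (0.586), with the first principal component removed (0.111), the median of probe sets, quantile normalization again, and the 3′ minus 5′ difference or background as a covariate. None of the 12 pairs with the proximal tubule passed by r. For ribosomal proteins r was −0.536 (adjusted permutation p 0.0949), rho was −0.635 (0.0376) and r without the 2 farthest arrays −0.742 (0.0120). Without those arrays r passed also with platelets (−0.661, 0.0354, against −0.479 with all arrays) and regulatory T cells (−0.638, 0.0420, against −0.419).

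**Figure D2:**
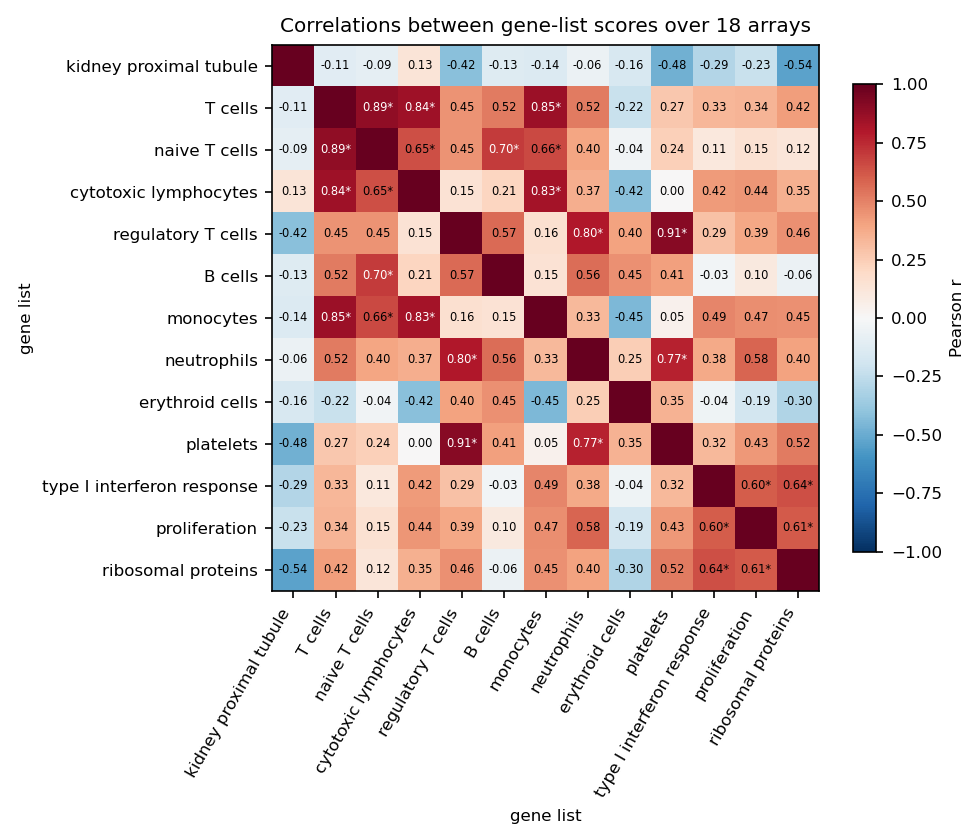
Pearson correlations between the scores of the 13 core lists over 18 arrays, with gene lists on both axes and the colour giving r from −1.0 to 1.0. An asterisk marks the 13 of 78 pairs with an adjusted permutation p below 0.05. T cells, naive T cells, cytotoxic lymphocytes and monocytes correlate at 0.645 to 0.886, and regulatory T cells correlate best with platelets, at 0.911.

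The regulatory T-cell score moved with a sign of RNA quality. Against the 3′ minus 5′ difference it had r = 0.795 (rho 0.742, permutation p = 0.00018 and 0.00063, adjusted p for r 0.00437 over 35 lists), and 0.757 without the 2 farthest arrays. Platelets (r 0.750, rho 0.732), immature neutrophils (0.705, 0.676), brain (0.702, 0.631), neutrophils (0.635, 0.678), eosinophils and basophils (0.614, 0.664) and dendritic cells (0.605, 0.604) also rose with the difference. Their p ran from 0.00025 to 0.00761 for r (adjusted 0.00437 to 0.0333) and from 0.00072 to 0.00904 for rho, and r without the 2 farthest arrays from 0.512 to 0.775. Calcineurin and NFAT genes had r = −0.670 (adjusted p 0.0176) and rho −0.453 (p = 0.0599), and the relation rests on the 2 farthest arrays, with −0.386 without them. Oxidative phosphorylation did not pass by r (0.553, p = 0.0175, adjusted 0.0626), but rho was 0.703 (p = 0.00143) and r without the 2 farthest arrays 0.750. For proliferation and ribosomal proteins r was 0.431 and 0.444 (p = 0.0733 and 0.0657, both adjusted 0.171), rho 0.60 and 0.515 (p = 0.00953 and 0.0309) and r without those arrays 0.625 and 0.669. Glycolysis and hypoxia had r = −0.547 (p = 0.0179, adjusted 0.0626), rho −0.573 (p = 0.0146) and −0.649 without those arrays, and skeletal muscle 0.439 (p = 0.0666, adjusted 0.171), 0.647 (p = 0.00452) and 0.317. For the cytotoxic score r was 0.0207 (rho 0.0485, p = 0.937 and 0.851). For the proximal tubule r was −0.40 (p = 0.101, adjusted 0.207), rho −0.614 (p = 0.0081) and r without the 2 farthest arrays −0.496.

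**Figure D3:**
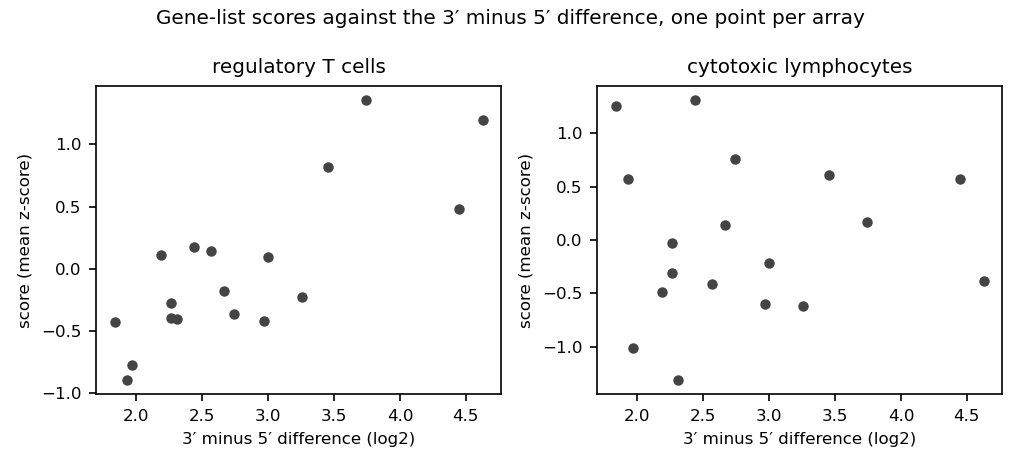
Scores of regulatory T cells (left) and cytotoxic lymphocytes (right) on the y axis, as mean z-scores, against the 3′ minus 5′ difference of the control probe sets (x axis, log2), with 1 point per array. Regulatory T cells rise with the difference at r = 0.795, and cytotoxic lymphocytes have r = 0.0207.

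The cytotoxic score asked which genes followed cells carrying granzymes and perforin. With limma, 146 genes were higher and 4 lower at a higher score, of 8939 tested, and with array weights 211 and 35. Chemokines were among the steepest: CXCL11 rose by 1.81 ± 0.26 log2 per SD of the score (SE, n = 18, adjusted p = 0.000693), CXCL9 by 1.55 ± 0.16 (1.23e-05), CCL4 by 1.40 ± 0.11 (1.6e-07) and CXCL10 by 1.35 ± 0.19 (0.000527). The class II gene HLA-DRB4 rose by 1.40 ± 0.27, although its probe sets disagreed, and the survival gene BCL2A1 by 1.18 ± 0.19. The 4 lower genes were the amino acid transporter SLC7A5 (−0.51 ± 0.13), GP2 (−0.51 ± 0.13), MST1 (−0.41 ± 0.09) and the proline dehydrogenase PRODH (−0.34 ± 0.09). The 6 higher genes kept their calls in every leave-out, whereas those 4 lost them in 13, 10, 2 and 13 of 18. The slope of GP2 was −0.30 without array 16, and MST1 lost its call without array 1 or 16 (−0.28 without array 16). GP2 kept its call without arrays 4, 5, 6, 8, 9, 12, 17 and 18, SLC7A5 without 4, 7, 9, 10 and 14, and PRODH without 2, 4, 9, 12 and 14. These 3 also lost their calls with the first principal component removed and without the 3 arrays of largest 3′ minus 5′ difference, and PRODH with only genes above the median gene.

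Of the lists, interferon gamma response had the most members higher at a higher cytotoxic score. In all, 9 of its 12 members were higher (11 when adjusted over the list alone), among them TAP1 and GBP1, a guanylate-binding protein chosen after its values were seen, at 0.78 ± 0.12. Of natural killer cell genes 5 of 6 were higher (5 adjusted over the list alone, 3 without array 12), namely CD160, IL18RAP, IL2RB, KLRF1 and XCL1. Of T-cell genes 5 of 9 were higher (5 adjusted over the list alone), namely CD2, CD247, CD3D, CD3G and LCK. Of monocyte genes 5 of 11 were higher (8 adjusted over the list alone), namely CD86, CLEC7A, CTSS, FCN1 and LYZ, the last by 1.08 ± 0.16. Of inflammatory genes 4 of 8 were higher (5 adjusted over the list alone, 2 without array 12, 13 or 17), namely CCL4, CXCL8, IL1B and TNFAIP3. With limma, 0 of 22 type I interferon genes, 0 of 15 proximal tubule genes, 0 of 7 B-cell genes and 0 of 6 plasma-cell genes passed, also when adjusted over the list alone. With the T-cell score as a covariate, 3 genes remained of the 150, 2 of them in the interferon gamma list, and CXCL11, CXCL9 and CCL4 kept their calls, while 1095 of 8939 genes had an unadjusted p below 0.05 (686 without the covariate).

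The proximal tubule score asked which genes followed the main epithelium of the arrays. With limma, 442 genes were higher and 205 lower, of 8939 tested. With the first principal component removed 323 were higher and 434 lower, so that most were lower, and with array weights 1646 and 1205. The steepest rises were HPD, an enzyme of tyrosine breakdown, by 1.35 ± 0.14 log2 per SD (SE, n = 18, adjusted p = 9.56e-06), FABP1, a fatty acid binding protein, by 1.24 ± 0.16 (7.21e-05), CRYAA by 1.03 ± 0.17, the anion transporter gene SLC17A3 by 0.99 ± 0.14, the bile acid transporter gene SLC10A2 by 0.98 ± 0.13 and NPL by 0.97 ± 0.12. The steepest falls were HSD17B2, a steroid dehydrogenase, at −1.14 ± 0.23 (0.00285), the matrix protein TNC at −0.81 ± 0.15, PCP4 at −0.80 ± 0.15, GPM6B at −0.80 ± 0.15, LTBP1, which binds latent TGF-beta, at −0.75 ± 0.11 and TSPAN8 at −0.73 ± 0.20 (0.0261). TSPAN8 lost its call without array 8 (−0.62), with arrays centred (−0.69), with the first principal component removed (−0.53) and with background as a covariate (−0.65). The other 11 kept theirs in every leave-out and every other setting.

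Array 16 had the lowest proximal tubule score, −1.95, with the next at −1.09. Without it 2301 genes passed, and without array 8 the number was 415. The slopes without array 16 were 0.73 for FABP1, 0.60 for NPL, 0.64 for SLC10A2, 0.55 for SLC17A3 and −0.48 for TNC. Of podocyte genes, 2 of 7 rose with the score, NPHS1 (0.41 ± 0.08) and WT1 (0.44 ± 0.11), or 3 adjusted over the list alone. Of loop and distal tubule genes 2 of 8 rose, CALB1 (0.56 ± 0.14) and the thiazide-sensitive transporter gene SLC12A3 (0.40 ± 0.09). Adjusted over the list alone, 2 rose and 3 fell, and without array 8 or 16 the count was 1. Of collecting duct genes 2 of 8 rose, FOXI1 (0.42 ± 0.08) and ATP6V1B1 (0.43 ± 0.09), both markers of intercalated cells, or 2 adjusted over the list alone, and 4 rose without array 16. Of 9 T-cell, 15 cytotoxic and 12 interferon gamma genes 0 passed, also adjusted over the list alone. Of 11 monocyte genes VCAN was lower (−0.68 ± 0.17) and HMOX1 higher (0.56 ± 0.08), 1 each also adjusted over the list alone, and 5 were lower without array 16.

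**Figure D4:**
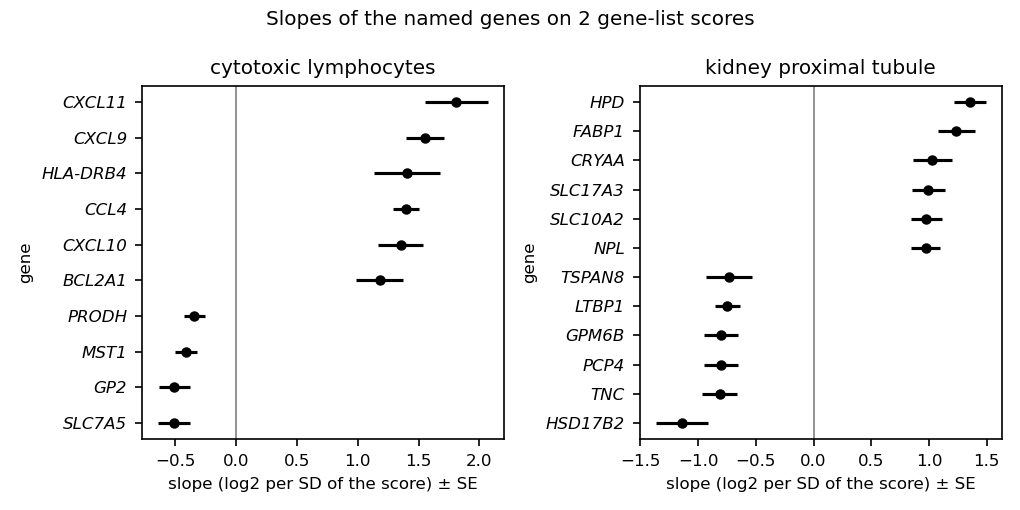
Slopes of the named genes (y axis) on the cytotoxic (left) and proximal tubule (right) scores, in log2 per SD of the score (x axis), from limma over 18 arrays. Points are estimates and bars 1 SE. CXCL11 has the steepest rise with the cytotoxic score, 1.81, and HPD with the proximal tubule score, 1.35, while HSD17B2 falls most, at −1.14.

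The regulatory T-cell score asked which genes followed markers such as FOXP3 and CTLA4. With limma, 838 genes were higher and 1132 lower, of 8951 tested, and with quantile normalization again 1114 were higher and 794 lower. The steepest rises were FABP4, a fatty acid binding protein of fat cells, by 0.96 ± 0.26 log2 per SD (SE, n = 18, adjusted p = 0.0127), KLRB1, a receptor of natural killer and T cells, by 0.90 ± 0.24, the fatty acid transporter CD36 by 0.89 ± 0.24, CSTA by 0.75 ± 0.24, S100A8 by 0.74 ± 0.21 and TDO2 by 0.73 ± 0.23. The steepest falls were the chromatin subunit SS18 at −1.07 ± 0.10 (1.48e-05), SGPP1 at −0.97 ± 0.13, MPHOSPH8 at −0.93 ± 0.17, GLTP at −0.90 ± 0.12, SLC17A5 at −0.87 ± 0.14 and the translation factor EIF2S3 at −0.87 ± 0.16. With the median of probe sets SS18 was at −0.30 and S100A8 at 0.39. With the first principal component removed the calls of CD36 (0.41), TDO2 (0.39), S100A8 (0.23), KLRB1 (0.19) and CSTA (0.04) ended. FABP4 and the 6 lower genes kept theirs there. The T-cell score as a covariate ended the calls of KLRB1, CSTA, S100A8 and TDO2, and FOXP3 alone as the score those of FABP4, CD36, CSTA and TDO2. The 6 lower genes kept their calls in every leave-out. The higher ones lost them without array 5 (FABP4, 0.70, and CD36, 0.75), without array 2 (KLRB1, 0.68, S100A8, 0.51, and CSTA, 0.59), without array 13 (TDO2, 0.68) and, for CSTA, also without arrays 8 and 13. TDO2 had a value in 11 of the 18 leave-outs, as it lay near the filter on level.

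The score that these genes followed had r = 0.795 with the 3′ minus 5′ difference. With the 3′ minus 5′ difference as a covariate 23 genes passed (12 higher, 11 lower), 571 without the 3 arrays of largest difference, and 1105 without array 2. Of the 12 genes named above only SS18 kept its call with that covariate (−0.92). The slopes of KLRB1, FABP4, CSTA and S100A8 were 0.74, 0.55, 0.54 and 0.52, and 1615 genes had an unadjusted p below 0.05. Those of TDO2 and CD36 fell to 0.35 and 0.22. For SGPP1, GLTP, SLC17A5, EIF2S3 and MPHOSPH8 the slopes shrank to −0.64, −0.48, −0.30, −0.22 and −0.18. The relation of covariate and score widens the SE, so a lost call alone does not show a lost slope. With background, the mean of the lowest 25 percent of genes, as a covariate 0 passed in limma and 378 had an unadjusted p below 0.05, and the slope of CD36 turned to −0.39. Those of KLRB1 and TDO2 rose to 1.47 and 1.29, also not past the threshold. The slopes of SS18, MPHOSPH8, EIF2S3 and GLTP shrank to −0.0953, −0.0363, −0.28 and −0.38, and that of FABP4 to 0.18. This covariate had r = 0.951 with the score, so the loss of calls was nearly fixed. Of 23 ribosomal protein genes 9 were higher and 1, RPL8 (−0.36 ± 0.06), lower (9 and 1 adjusted over the list alone; higher without arrays 2, 5 and 8 were 4, 2 and 5, and 2 were lower without array 9). Of oxidative phosphorylation genes 6 of 16 were higher (10 adjusted over the list alone; 2 without array 3, 5 or 8, 3 without array 2 and 11 without array 9), NDUFA1 and UQCRB both by 0.24. Of proximal tubule genes 5 of 15 were lower, CUBN, LRP2, PCK1, SLC22A8 and SLC3A1 (6 adjusted over the list alone; 1, 2 and 3 without arrays 2, 5 and 13). Of T-cell genes 4 of 9 were higher, CD3D, CD3E, CD5 and CD6, and MAL was lower (4 and 1 adjusted over the list alone; 0 higher and 0 lower without array 2, 2 higher without array 8 and 1 without array 13). Of calcineurin and NFAT genes 3 of 8 were lower, NFATC3, PPP3CA and PPP3R1 (5 lower and 1 higher adjusted over the list alone; 1 without array 2, 7, 8, 12, 13, 14 or 17). Each of these list counts was 0 with the 3′ minus 5′ difference as a covariate.

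The number of genes following the type I interferon score depended on the method. With limma, 2 of 8932 genes were higher and 0 lower, and 1569 had an unadjusted p below 0.05. With array weights 814 were higher and 1530 lower. The 2 genes were UBE2L6, a conjugating enzyme for the ubiquitin-like protein ISG15, by 0.44 ± 0.08 log2 per SD (SE, n = 18) and NFE2L3 by 0.36 ± 0.06, both with an adjusted p of 0.0484. In 13 of 18 leave-outs 0 genes passed. The count was 3 without array 3 or 12, 2 without array 11, 1 without array 15 and 8 without array 16. Both genes also lost their calls with quantile normalization again, without a filter on level, with the first principal component removed, and with the 3′ minus 5′ difference or background as a covariate. Of the 12 interferon gamma genes 0 passed over all genes and 10 were higher when adjusted over the list alone. For the erythroid score, of red-cell genes, limma called 0 of 8946 genes, with 1898 at an unadjusted p below 0.05. The members of this list did not vary together (mean r −0.00857, against 0.0141 for random lists), so its score may not measure red cells. Limma called 183 genes without array 6, 74 without array 16, 38 without array 17, 15 without array 1, 9 without array 2 and 6 without array 12. It called 1979 with only genes above the median gene, where the score rested on 7 of 14 members. It called 1457 with background as a covariate, 1089 with array weights, 437 with the first principal component removed and 169 with the mean log2 level as the score.

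Among the 5969 genes above the median gene, 109 had an SD over 1, against a median SD of 0.36. The most variable were JCHAIN, the joining chain of antibodies (8.49 ± 1.86), HLA-DRB4 (8.61 ± 1.86), CXCL9 (8.58 ± 1.70), the light chain gene IGLC1 (10.95 ± 1.70) and the mast cell protease CPA3 (6.95 ± 1.63). The other 20 of the top 25 had SDs from 1.34 to 1.62. They held the antibody genes IGLV1-44 and IGKC, the chemokine genes CXCL10, CCL4, CCL19 and CCL5, HPD, FABP1, the drug-metabolising enzyme CYP3A5, VNN1, PSPH, FGB, SPINK1, POSTN, FABP4, HLA-DQA1, GSTT1, the IgE receptor gene FCER1A, KLRB1 and MLIP. MLIP followed the antibody genes, with r = 0.880 with IGKC and 0.839 with IGLC1, pairs looked at after the values were seen and given with no test. Probe sets disagreed for HLA-DRB4 (SD 0.19 with the median of probe sets), IGLC1 (0.72), PSPH (0.96), POSTN (0.83), IGLV1-44 (0.60) and IGKC (0.58), and without array 16 the SD of FABP1 was 0.93. The median absolute deviation was 0.84 for FGB, 0.69 for GSTT1, 0.79 for FABP1, 0.81 for VNN1 and 0.99 for PSPH.

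Genes of the drugs' targets and of regulatory T cells had SDs between 0.17 and 0.54. FOXP3 was at 5.09 ± 0.33 (SD, n = 18), CTLA4 at 4.11 ± 0.33, IL2RA, the receptor for interleukin 2, at 4.46 ± 0.26 and IL2 at 3.20 ± 0.17. FKBP1A, the protein that binds both drugs, was at 8.45 ± 0.54, MTOR at 6.19 ± 0.23 and FKBP5, a glucocorticoid target, at 3.92 ± 0.47. The lower quartile of gene means was 4.84, so IL2, FKBP5, CTLA4 and IL2RA lay among the lowest 25 percent of genes. With the median of probe sets FKBP1A was at 7.53, MTOR at 5.33, FOXP3 at 4.43 and IL2 at 2.92.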

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

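The tests with background (the mean of the lowest 25 percent of genes) as a covariate, and those without the 3 arrays of largest 3′ minus 5′ difference, were chosen after the results were seen. The proximal tubule level (9.72 to 9.82 over the leave-outs), the 21 co-varying lists (19 to 24) and the 109 genes with an SD over 1 (80 to 114) kept their size when 1 array was left out. The 13 score pairs ranged from 8 (without array 13) to 17. Genes called ranged from 1105 (without array 2) to 2399 for regulatory T cells, 104 to 165 for cytotoxic lymphocytes, 0 to 183 for erythroid cells, 0 to 8 for type I interferon response and 415 (without array 8) to 2301 (without array 16) for the proximal tubule. With only genes above the median gene, 11 lists co-varied, 3 score pairs passed, 83 genes followed the cytotoxic score and 1979 the erythroid score; fewer genes were tested there, and the regulatory T-cell fit had too few members left to be run. With array weights the counts were 4095 for regulatory T cells, 246 for cytotoxic lymphocytes, 1089 for erythroid cells, 2344 for type I interferon response and 2851 for the proximal tubule. Without a filter on level they were 3414 for regulatory T cells, 4 for erythroid cells and 0 for type I interferon response. With the 3′ minus 5′ difference as a covariate they were 23 for regulatory T cells, 5 for erythroid cells and 0 for type I interferon response, and with the first principal component removed 437 and 0 for the last 2. With background as a covariate, whose r of 0.951 with the regulatory T-cell score nearly fixes the outcome there, 0 genes followed regulatory T cells, 1457 erythroid cells and 0 type I interferon response. Without the 3 arrays of largest difference 571 followed regulatory T cells, with fewer arrays tested. With the T-cell score as a covariate 3 genes followed the cytotoxic score. Where limma called 0 genes, those with an unadjusted p below 0.05 were 378 for regulatory T cells, and for type I interferon response 1837 without a filter, 1717 with the 3′ minus 5′ difference, 511 without the first principal component, 1408 with background and 2108 with quantile normalization again. Erythroid cells gave 11 genes with the median of probe sets, 1 with quantile normalization again and 169 with the mean log2 level as the score, which also gave 21 score pairs. Type I interferon response gave 0 genes with quantile normalization again and 8 with arrays centred. With background as a covariate the mean correlation of regulatory T cells turned to −0.0197 and that of brain to −0.0282, the score correlation of regulatory T cells with platelets to −0.0692 and that of neutrophils with platelets to −0.179, and the slope of CD36 on the regulatory T-cell score to −0.39. Apart from the fewer genes, lists, members or arrays named, the cause of these changes was not tested. Of the called items, 15 of 21 lists and 7 of 13 score pairs kept their calls in every leave-out, and 11 and 6 in every other setting. Of the named slopes 6 of 10 did so for cytotoxic lymphocytes, 11 of 12 for the proximal tubule, 6 of 12 for regulatory T cells and 0 of 2 for type I interferon response, and 3, 11, 0 and 0 in every other setting. Regulatory T-cell markers sat near background (8 of 11 in the lowest 25 percent of gene means), which limits what their levels can show.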

Other observations

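The tests in this part were chosen only after the results they bear on had been seen, except the permuted orderings and the fits with the 3′ minus 5′ difference or the T-cell score as a covariate, which were planned, although what they would show was written down later. An earlier test of background for the regulatory T-cell list, its mean correlation given background (−0.0193, against 0.369 for T cells), was replaced, because a covariate at r = 0.951 with the score nearly fixes its outcome. Earlier tests of RNA quality and background for the cytotoxic score, the called genes that stayed called with each as a covariate, were replaced, because a covariate nearly unrelated to the score could hardly end a call. An earlier test of leukocytes, the correlations of the proximal tubule score with T cells (−0.112), cytotoxic lymphocytes (0.130) and monocytes (−0.138), was replaced by 1 on the called genes, to which the value without array 16 was added later; without the 2 farthest arrays these r were −0.507, −0.140 and −0.432. The pairs of measures below form a family of 19, and every r comes from 18 arrays with Spearman's rho and permutation p-values.

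Interferon gamma genes moved with the scores of monocytes and lymphocytes. Their score correlated with monocytes at r = 0.904 (rho 0.899) and with cytotoxic lymphocytes at 0.898 (0.95), both at a permutation p of 1e-05 for r and rho, the smallest possible (adjusted 6.33e-05), with T cells at 0.746 (0.773, p = 0.00046 and 0.00027, adjusted p for r 0.00125) and with type I interferon response at 0.581 (0.527, p = 0.0113 and 0.0263, adjusted 0.0215). Without the 2 farthest arrays these r were 0.848, 0.872, 0.659 and 0.561. Plasma cells did not pass with cytotoxic lymphocytes (0.159), T cells (0.275) or B cells (0.0857), with rho 0.172, 0.319 and 0.131 and adjusted permutation p 0.590, 0.338 and 0.779.

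A list of 6 fat-cell genes (ADIPOQ, PLIN1, LIPE, CIDEC, LEP and CFD) had a mean pairwise correlation of 0.779, a value with no test, because the genes were chosen after their correlations with FABP4 had been seen. ADIPOQ was at 3.51 ± 1.44 and CFD at 7.59 ± 1.02. CPA3 correlated with FCER1A at 0.637 (rho 0.637, p = 0.00386 and 0.00549, adjusted 0.00815 and 0.0130), and at 0.606 without the 2 farthest arrays. For skeletal muscle, 7 of 11 members were highest on array 15, whose score was 2.48 (next 1.05), and the list's mean correlation without it was 0.432. Oxidative phosphorylation scores reached 1.88 and 1.87 on 2 arrays, with the next at 0.66. All 18 arrays belong to 1 group, so no biological explanation by treatment, time or outcome was tested.

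The genes following the regulatory T-cell score may reflect raised background signal rather than these cells. The measure of background was highest on array 5 (4.04), which had the narrowest interquartile range (2.89). It was lowest on array 3 (3.65), which had the widest (3.49). The measure therefore does not tell raised background from a narrower spread of all levels on an array. The score correlated at 0.951 (rho 0.940) with the mean of the lowest 25 percent of genes, its own members left out (permutation p 1e-05 for both, the smallest possible, adjusted 6.33e-05, and 0.932 without the 2 farthest arrays), and random lists of the same level correlated with the score at a median of 0.713 (quartiles 0.582 to 0.804). The correlation with the T-cell score was lower, at 0.452. That argues against the measured T-cell score as the sole cause, and leaves the T-cell share itself open. That score stands for the share only in part, as its member MAL ran against the others (mean r −0.327). The comparison also favours background, since 8 of the 11 regulatory T-cell markers lie in the same lowest 25 percent of genes. With background held fixed the partial r was 0.581 with T cells (permutation p = 0.0118, adjusted 0.0118 over 4 partial correlations) and 0.705 with naive T cells (0.00122, adjusted 0.00163). A contribution of T cells therefore stays open. Background also rose with the 3′ minus 5′ difference (r = 0.773, rho 0.769, p = 0.00025 and 0.00031, adjusted 0.000792 and 0.00118, and 0.670 without the 2 farthest arrays), so RNA quality and background stay open together. Of 100 orderings of the score, the real one included, 2 called as many genes (real 1970, highest other 2095). At 0.05 that argues against a chance order of the arrays if they are independent, although 1 ordering other than the real one called more genes. It does not tell causes apart.

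The genes following the cytotoxic score could come from RNA quality, from background or from the share of T cells. The score had r = 0.0207 with the 3′ minus 5′ difference (95% interval −0.451 to 0.483) and 0.00181 with background (−0.465 to 0.468). These values argue against either measure as the sole cause of the score's spread, and the intervals leave a part open. RNA quality and background themselves stay open, as the measures stand for them only in part. Each of the 150 called genes correlated with the score at 0.670 or more in size. Calling selects genes by that relation, so this floor decides nothing about causes. The interferon gamma and cytotoxic scores kept a partial r of 0.751 with the T-cell score held fixed (permutation p = 0.00034). That score stands for the T-cell share only in part, as its member MAL ran against the others (mean r −0.327). The partial r therefore argues against the measured T-cell score as the sole cause, and leaves the T-cell share itself open. The monocyte score, at r = 0.835 with the cytotoxic score, was not held fixed. Only 3 genes stayed called with the T-cell score as a covariate. At r = 0.845 with the cytotoxic score, that covariate leaves the fit little to separate them by. Of 100 orderings 1, the real one, called as many genes (real 150, highest other 71). That argues against a chance order of the arrays if they are independent, and it does not tell causes apart.

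The genes following the proximal tubule score could come from RNA quality, from leukocytes in place of tubules or from the share of cortex. With the 3′ minus 5′ difference as a covariate 425 of the 647 genes stayed called. For those genes that argues against the measured difference as the whole cause. At r = −0.40 with the score (rho −0.614), the covariate could hardly end most calls. The measure also stands for RNA quality only in part, so quality itself stays open. Leukocytes stay open, since the 205 lower genes had a median correlation of 0.0964 with the mean of the T-cell, cytotoxic and monocyte scores (quartiles −0.0382 to 0.234), but 0.278 without array 16 (0.136 to 0.407). The share of cortex stays open: the podocyte score rose with the proximal tubule score at r = 0.715 (rho 0.585, permutation p = 0.00092 and 0.0128, adjusted 0.00218 and 0.0243), but at 0.581 without array 16 (p = 0.0133), which was lowest in both, and at 0.384 without the 2 farthest arrays. Endothelium and fibroblasts fell as the proximal tubule score rose, at r = −0.479 (adjusted permutation p 0.0754) and rho −0.606 (0.0194). Without the 2 farthest arrays their r was −0.633, but 0 of their 12 genes passed in the fit. For the collecting duct r was 0.298 (0.320), rho 0.482 (0.0661) and r without those arrays 0.721. Neither relation was tested as a cause. Of 100 orderings 1, the real one, called as many genes (real 647, highest other 2). That argues against a chance order of the arrays if they are independent, and it does not tell causes apart.

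For the type I interferon response 4 of 100 orderings called as many genes (real 2, highest other 9). At 0.05 that argues against a chance order if the arrays are independent, for this score alone, with no adjustment over the 5 scores. In 13 of 18 leave-outs 0 genes passed. The erythroid score called 0 genes, so that all 100 of 100 orderings called at least as many (highest other 171) by construction, which says nothing about chance.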
